A study of Mus musculus with 8 samples.

How the data were processed

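RNA of whole testis from 8 mice aged 27 days was measured on Affymetrix arrays, 1 array per mouse and 4 mice per genotype, per the labels. RNA was extracted with Trizol, purified on columns and turned into biotin-labelled cRNA, per the labels' protocols. The deposited values are intensity values on a linear scale from GCOS, per the submitters' processing notes. Its version and settings are not given in the sources used here. In the deposited intensity table every array has the same mean, 500, after trimming 2% of probe sets at each end, so each array was scaled to a common target. A scaling of this kind keeps differences in the shape of the distribution between arrays. The table gives no detection calls, so how far a dim probe set lay above background is unknown, and 154 to 218 probe sets per array were below 1.

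The table held 45101 probe sets, of which 64 AFFX control probe sets were kept out of the tests. Of the other 45037, the platform annotation gave 34945 a single gene symbol, 932 several and 9160 none. Symbols were updated through Entrez identifiers for 34741 probe sets, and chromosomes were taken from a RefSeq gene table of assembly GRCm38.p6. No coordinates are given, since the files name no build. Values were taken as log2(value + 16), so a fold change is on the log2(value + pseudocount) scale and understates the change of dim genes. Probe sets whose mean over the 8 arrays lay above the 40th percentile were kept, 27022 in all. A gene was represented by its probe set with the highest mean, which gave 13787 genes. Other probe sets of a gene could disagree: of 475 genes called with the replicate block 145 had more than 1 probe set, 61 of these had a probe set of the opposite sign, and 1 had a probe set called in the opposite direction.

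Genotypes were compared with limma (version 3.58.1, R 4.3.3), using lmFit and eBayes with an intensity trend, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Adjusted p-values and counts of genes come from this test unless another is named. Gene lists, 26 in all with 778 entries of which 666 were on the array, were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. Members of a list were also adjusted over the list alone. The lists cover spermatid, meiotic and spermatogonial genes, markers of other cell types of the testis and its surroundings, and general pathways. Named genes were Brwd1, Brwd3 and Phip, then up to 10 genes with the largest rise and 10 with the largest fall past the threshold without overlap between genotypes, and up to 4 members of each list with the smallest p. The same rule was applied to the replicate block. Clone-named and predicted genes were ranked and could be summarised. The samples, the tests, the lists, the rule and most alternatives were fixed before the data were examined.

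Both genotypes share the replicate numbers 1 to 4 in the labels. Deviations from the genotype means correlated between mice of the same number (r between 0.518 and 0.618 in the 4 pairs), which by the rule set beforehand counts as pairing. Only 2 of the 8 mice were closest to their own number in the other genotype. The correlation followed a split of replicates 1 and 2 from replicates 3 and 4 instead, which also appeared in the control transcripts, so a block of these batches was added after seeing the data. Blocked values are printed where they change a call. The source of the pairing is the data, not a statement in the labels.

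The gene test was tested on simulated data for the comparison of mutant with wild type, with the means, spreads and batch differences of these arrays and 200 of the 13787 genes changed. Of genes changed by 2 log2 units 97% were recovered without a block and 100% with either block. Of genes changed by 1 log2 unit 46% were recovered without a block, 86% with the replicate block and 89% with the batch block. False calls numbered 0, 14 and 10. The simulated genes varied independently of each other, and no simulated mouse stood apart. In the real arrays the spermatid nuclear protein list had an estimated correlation of 0.957. The simulated rates therefore need not hold for the real calls. Alternatives covered quantile normalization, median centring, pseudocounts of 1 and 64, other filters, no trend, robust eBayes, array weights, the mean of a gene's probe sets, a stricter threshold, other list tests, and leaving out each mouse. Figures were drawn with matplotlib 3.10.9.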

Results

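Gene expression was measured in whole testes of 27-day-old mice, 4 labelled wild type and 4 labelled as mutant for Brwd1, a gene of the bromodomain and WD repeat protein family. Each mouse gave 1 array, so p-values measure the spread between mice. Without a block, that spread also holds the difference between the batches of replicates. At this age, per the series' design text, germ cells have passed meiosis and spermatids are partway through their development, and the comparison asks which transcripts differ in testes of mutants. The labels disagree on the controls: their titles say wild type, while their genotype entry reads Brwd1+/-. The controls may therefore be carriers of 1 mutant copy, and they are called wild type here as in their titles. Each array held 45101 probe sets with a trimmed mean of 500, and median intensities lay between 90.7 and 124. The number of arrays limits the precision of every value.

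Brwd1 itself was not called lower in mutants, and its probe sets disagreed in sign. The probe set that represented it gave 290 ± 46.7 in wild type and 365 ± 71.0 in mutants (SD, n = 4 each), a log2 difference of 0.31 with a standard error of 0.19 (limma, adjusted p = 0.766). In wild-type replicates 1 to 4 it read 303.9, 222, 305.7 and 328.6, and in mutant replicates 1 to 4 it read 413.4, 436.1, 324.3 and 286.9. The 3 other kept probe sets had negative log2 differences, -0.28, -0.20 and -0.04. None of the 5 Brwd1 probe sets passed the test between genotypes. The labels do not say what the mutation is, so a probe set outside an altered part of the transcript checks nothing about the genotype. The related genes Brwd3 (log2 difference -0.05) and Phip (0.02, and -0.27 to 0.83 over its other kept probe sets) were not called either.

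The arrays separated first by replicate number and then by genotype. The first principal component, with 53.6% of the variance, set replicates 1 and 2 of both genotypes apart from replicates 3 and 4, and the second, with 25.6%, set mutants apart from wild type. Between these batches 10908 of 27022 probe sets differed. The epididymis list was 4.54 log2 units higher in replicates 3 and 4 of both genotypes, and 14 of its 16 measured genes passed the test in that direction. Lcn5, a lipocalin secreted by the epididymis, averaged 48.5 in replicates 1 and 2 and 12300 in replicates 3 and 4. The bacterial poly-A control transcripts were lower in replicates 3 and 4 on all 24 of their probe sets. The 18 probe sets of the hybridization controls were lower there too, by 0.31 to 0.90 log2 units, as was the 5' probe set of the actin control (-0.83, against -0.39 for its 3' probe set). The labels name no batch. Since each batch held 2 mice of each genotype, comparisons are given without a block, as planned, and with blocks.

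**Figure D1:**
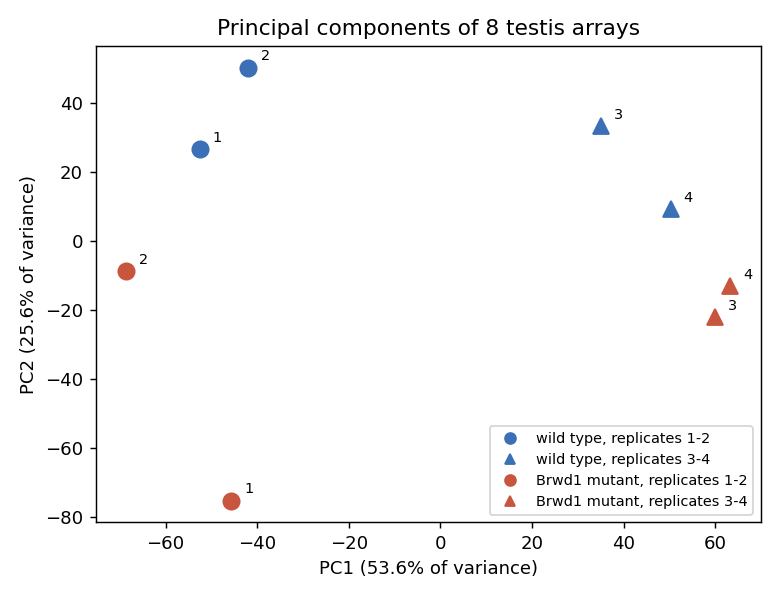
Scores of the 8 arrays on the first and second principal components of log2 intensity, coloured by genotype, with the replicate number beside each point. Circles (replicates 1 and 2) have negative scores on the first component and triangles (replicates 3 and 4) positive ones, and mutant replicate 1 lies at -75.3 on the second.

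**Figure D2:**
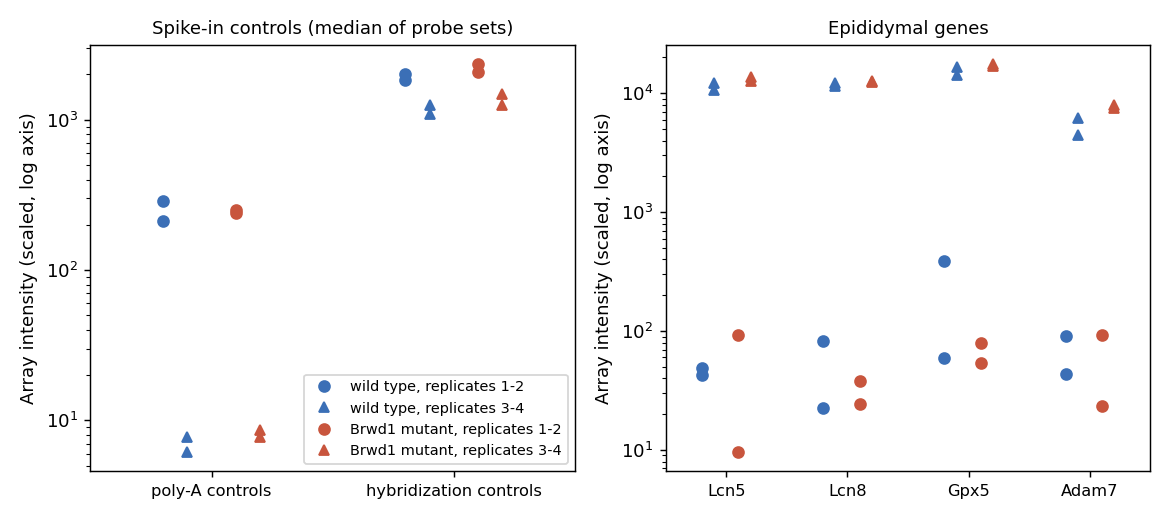
Intensity per array on a log axis for control transcripts added to the samples (left, median of the probe sets of each kind) and for 4 epididymal genes (right). Replicates 3 and 4 of both genotypes have poly-A control medians between 6.2 and 8.6, against 213.5 to 288.2 in replicates 1 and 2, and the epididymal genes are brighter there in both genotypes.

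Most genes that differed between genotypes were lower in mutants. Prm2, a protamine that packs sperm DNA, fell 18.1-fold, from 18329 ± 4956 to 1266 ± 911 (SD, n = 4 each; limma, adjusted p = 0.032). Prss51, a serine protease gene, fell 9.73-fold, Ubqlnl, a ubiquilin-like gene, 9.55-fold, and Fam71a 8.91-fold. Trp53tg5, Paqr5 and Mgat4e fell between 7.51-fold and 8.49-fold, and the clone-named or predicted genes Gm21283, 1700009J07Rik and 1700012A03Rik between 8.76-fold and 9.29-fold. Rises were fewer: the homeobox gene Six4 rose 2.15-fold, from 73.3 ± 11.2 to 176 ± 17.8, and the clone-named gene E230013L22Rik rose 2.98-fold.

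Of 13787 genes tested without a block, 39 passed an adjusted p of 0.05, 37 lower and 2 higher in mutants, all by at least 2-fold. With the replicate number as a block the count was 475 (430 lower, 45 higher), of which 334 changed at least 2-fold, and with the batch as a block, chosen after seeing the data, it was 363 (298 lower, 65 higher). All 39 genes were among those called in both blocked fits, which shared 324 calls. On single probe sets the counts were 30 of 27022 without a block, 630 with the replicate block and 477 with the batch block. In 725 genes all 4 mutant values lay below all 4 wild-type values and in 349 genes above them, together 7.79% of genes where chance gives 2.86%. The unblocked count changed as single mice were left out, which also makes the batches uneven between genotypes. It was 0 without wild-type replicate 1, 2 or 3 or mutant replicate 3, 20 without mutant replicate 4 and 185 without mutant replicate 1. Within replicates 1 and 2 alone no gene passed limma's test, and within replicates 3 and 4 alone 27 did. With mutant replicate 1 left out, the batch-blocked count was 630.

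The list of spermatid nuclear protein genes was lower as a group. It also held Spem1 and Gsg1, whose proteins are not nuclear and whose log2 differences were -3.20 and -1.84. Of 15 measured members, all had negative log2 differences, with a mean of -2.60. Without a block 1 passed over all genes and 14 passed adjusted over the list alone. With the replicate block 12 fell, and with the batch block 6. Tnp2 and Tnp1, transition proteins that replace histones, had log2 differences of -4.26 and -3.32, and the protamine Prm1 -3.28. These were -3.50, -2.64 and -2.66 without mutant replicate 1. The other kept probe set of Tnp1 had a log2 difference of -0.67 and was not called (adjusted p = 0.0703 with the replicate block). Cdyl, a member called with both blocks, had one of -1.86 on the probe set that represented it. Its other kept probe sets gave 0.14 and 0.31 and were not called. The intensities of Tnp2, Tnp1 and Prm1 went from 12814 ± 3715 to 917 ± 698, from 24319 ± 4124 to 3272 ± 2349, and from 21233 ± 5028 to 2943 ± 2405. These 3 genes missed the threshold without a block (adjusted p = 0.0551, 0.0735 and 0.0735) and passed with the replicate block (0.0159, 0.0214 and 0.0214) and the batch block (0.0237, 0.0331 and 0.0345). Prm1, Prm2 and Tnp2 lie on chromosome 16, as Brwd1 does, and Tnp1 on chromosome 1 (assembly GRCm38.p6). The list's call (camera, adjusted p = 2.73e-22) was lost at adjusted p = 0.332 with an estimated correlation. Its mean shift was -3.28 within replicates 1 and 2 and -1.92 within replicates 3 and 4, and -1.98 without mutant replicate 1, the mouse with the lowest level.

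**Figure D3:**
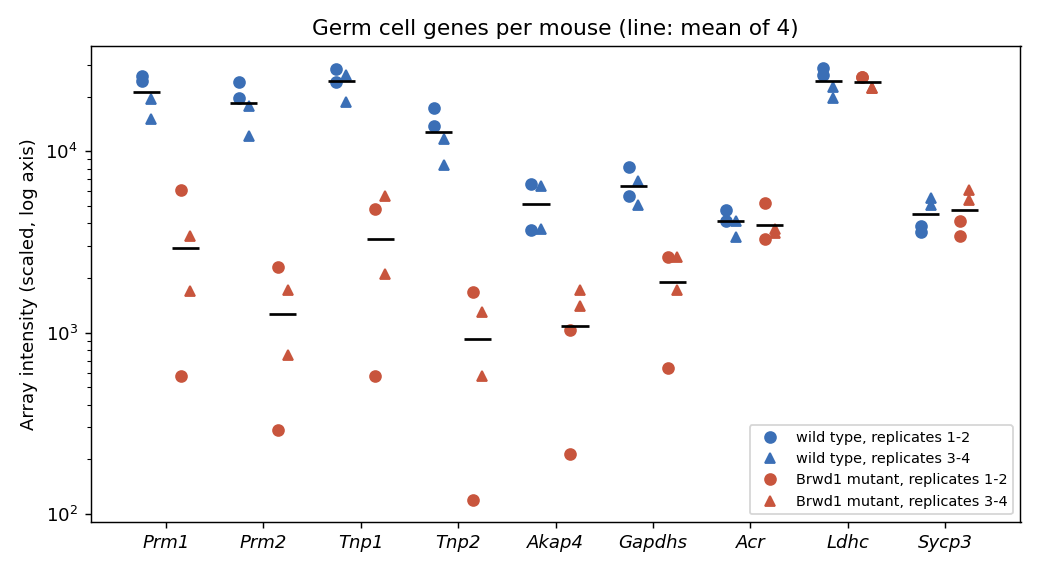
Array intensity per mouse on a log axis for 9 germ cell genes, with a line at the mean of 4 mice. All 4 mutants lie below all 4 wild-type mice for the protamine and transition protein genes, Akap4 and Gapdhs, while the genotypes overlap for Acr, Ldhc and Sycp3.

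Genes of the sperm tail and of the acrosome were lower too, by less. Among 37 tail genes the mean log2 difference was -1.04, and 1 fell without a block (Spata18, 6.79-fold), 18 adjusted over the list alone, 10 with the replicate block and 6 with the batch block. Tssk6, Tssk2 and Tssk3, kinases specific to the testis, fell 18.2-fold, 4.86-fold and 4.61-fold with the replicate block (adjusted p = 0.0214, 0.0261 and 0.0273). Tssk6 read 8.9 in mutant replicate 1, and its log2 difference of -4.19 was -3.34 without that mouse. Among 23 acrosome genes the mean was -0.83, and -0.50 without mutant replicate 1. None fell over all genes without a block, 5 did adjusted over the list alone, 2 with the replicate block and 1 with the batch block. Actrt1 and Capza3 fell 2.47-fold and 4.71-fold with the replicate block, and Actrt1 also with the batch block. Without mutant replicate 1 the log2 difference of Capza3 went from -2.24 to -1.54. Izumo1, which sperm need to fuse with the egg, had a log2 difference of -1.80 (adjusted p = 0.219), and -1.20 without mutant replicate 1. Acr, the gene of the protease acrosin, singled out after its values were seen, had one of -0.07. Both list calls (camera, adjusted p = 1.06e-17 and 2.7e-08) were lost, each at adjusted p = 0.332 with an estimated correlation. The tail list shifted by -1.37 within replicates 1 and 2 and by -0.71 within replicates 3 and 4, and the acrosome list by -1.21 and -0.44.

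Lists of other genes used after meiosis were split between members that fell and members that barely differed. Of 24 germ cell isozymes of energy metabolism, 6 fell adjusted over the list alone, 5 with the replicate block and 3 with the batch block. Gapdhs, the spermatid form of a glycolytic enzyme, fell 3.78-fold and Pgk2 1.81-fold with the replicate block, while Ldhc, singled out after its values were seen, read 24298 ± 4077 and 23980 ± 1817. The list's mean was -0.47 and its median -0.01 (camera, adjusted p = 0.00301, and adjusted p = 0.426 with an estimated correlation). Of 33 genes listed as regulators of transcription and RNA after meiosis, 3 fell both adjusted over the list alone and with the replicate block. These were Hspa1l (9.23-fold), Fhl5 (5.22-fold) and Rfx3 (2.10-fold). Hspa1l, the largest fall of the list, encodes a chaperone, and the list's median was -0.03. With the batch block Fhl5 was not called, its adjusted p lying just above the threshold. Without mutant replicate 1 the log2 difference of Hspa1l went from -3.21 to -2.56 and that of Fhl5 from -2.38 to -1.71. The other kept probe set of Rfx3 had one of 0.02, and the mean of both gave -0.52. The list of regulators (mean -0.30, camera adjusted p = 0.0135) was not called without wild-type replicate 2 (adjusted p = 0.0995), within replicates 3 and 4 (-0.18, adjusted p = 0.184), with the batch block and mutant replicate 1 left out (-0.20, adjusted p = 0.147), with the replicate block and number 1 left out (adjusted p = 0.0524), nor with an estimated correlation (adjusted p = 0.426). Of 7 measured multicopy sex-linked spermatid genes, 4 fell adjusted over the list alone and 3 with the replicate block, Cypt1, Cypt3 and Cypt4. Cypt4, listed with its sex-linked relatives, lies on chromosome 9 and alone fell with the batch block (adjusted p = 0.0447, against 0.0718 for Cypt1 and 0.0795 for Cypt3). Near-identical copies of such genes may share probes. Their list (mean -0.66, camera adjusted p = 0.0172) was not called with the batch block (adjusted p = 0.0657), nor with an estimated correlation (adjusted p = 0.332). Its call was also lost with array weights (0.0535), within replicates 1 and 2 (-0.88, 0.0721) and within replicates 3 and 4 (-0.44, 0.0574).

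Genes of earlier germ cell stages were mostly not called. Of 43 meiotic prophase genes none passed without a block, and 1 fell with either block: Syce2, a synaptonemal complex gene, from 6381 ± 546 to 4570 ± 396. The list's mean was -0.05 (camera, adjusted p = 0.319), -0.12 within replicates 1 and 2 and 0.02 within replicates 3 and 4. Sycp3, singled out after its values were seen, had a log2 difference of 0.07. None of 24 genes of the piRNA pathway, which silences transposons in germ cells, passed in any of the 3 fits, and the mean was 0.04 (adjusted p = 0.792).

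**Figure D4:**
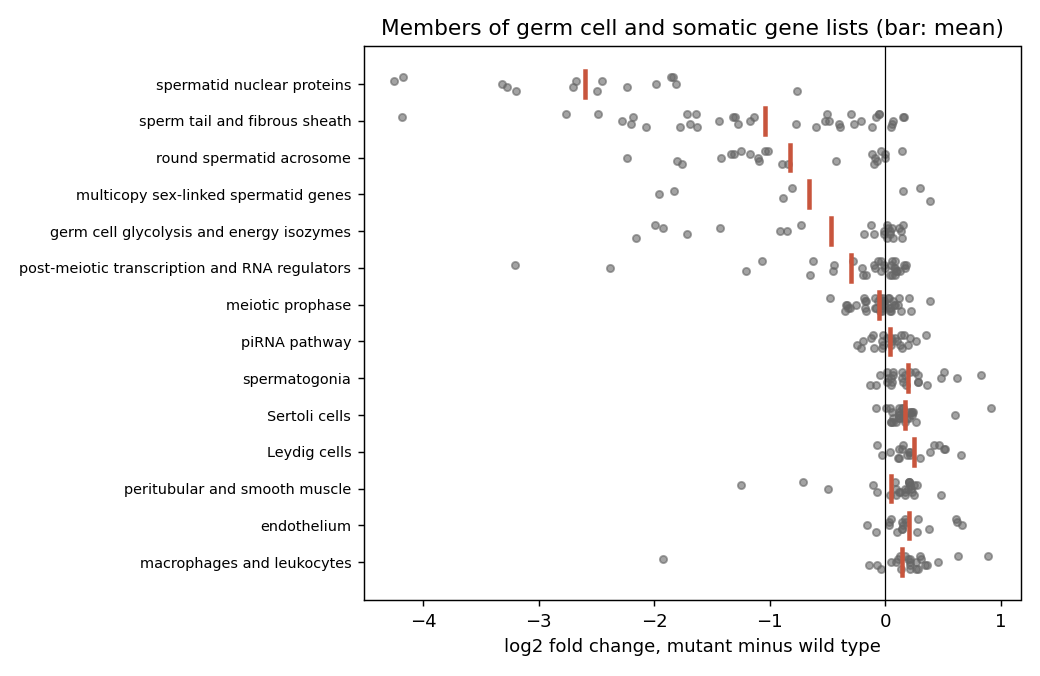
Log2 fold change, mutant minus wild type, of each measured member of 14 gene lists (grey points), with a bar at each list's mean. Means run from -2.60 for spermatid nuclear proteins to 0.25 for Leydig cells.

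Marker lists of spermatogonia and of several somatic cell types were slightly higher in mutants. The median log2 difference of all genes tested was itself 0.065, which is part of each mean. The mean log2 difference was 0.19 over 26 spermatogonial genes, 0.17 over 31 Sertoli cell genes, 0.25 over 19 Leydig cell genes, 0.21 over 18 endothelial genes and 0.15 over 25 genes of macrophages and leukocytes. These lists passed without a block (camera, adjusted p = 0.0359, 0.0226, 0.0135, 0.0226 and 0.0416). None of the 5 held with an estimated correlation, the adjusted p being 0.332, 0.566, 0.332, 0.426 and 0.332. Each call was also lost in some unblocked fits that left out 1 mouse. Such fits make the batches uneven between genotypes, so a loss need not come from the mouse left out. The call was lost for spermatogonia without wild-type replicate 1 or mutant replicate 1 or 4 (camera, adjusted p from 0.0647 to 0.0723). For endothelium it was lost without wild-type replicate 1 or 2 or mutant replicate 4 (0.0778 to 0.137). Macrophages lost it without any 1 of 6 of the 8 mice (0.0596 to 0.118). After quantile normalization only the Leydig list of the 5 kept its call. With median centring the Sertoli and macrophage lists lost theirs (camera, adjusted p = 0.0503 and 0.0527). Single members rarely passed. With the replicate block the spermatogonial genes Utf1 and Ccnd2 rose, with overlapping groups and without a call with the batch block (adjusted p = 0.105 and 0.104), and the 5 other kept probe sets of Ccnd2 were not called. Sox17 of the endothelium list rose 1.53-fold with the replicate block and the Fc receptor gene Fcgr3 1.55-fold, while Aif1 fell 3.80-fold within the macrophage list. In that list 21 of 25 members had positive log2 differences. Aif1 was not called with the batch block (limma, adjusted p = 0.0841). Its log2 difference went from -1.93 to -1.36 without mutant replicate 1. Cypt3 of the multicopy spermatid list changed much alike, from -1.96 to -1.39. With the batch block Sox17, Cldn5 and Fcgr3 rose. Which cells of the testis gave the signals of Sox17 and Aif1 was not tested. The Sertoli shift without mutant replicate 1 was 0.07 (camera, adjusted p = 0.382), and 0.11 when the batch block was used as well (0.0645). Its call was lost too without wild-type replicate 4 or mutant replicate 2 (0.209 and 0.152). The Sertoli shift was 0.31 within replicates 1 and 2 and 0.04 within replicates 3 and 4. The Leydig shift was 0.09 and 0.41, and lost its call without wild-type replicate 4 (adjusted p = 0.116). The lists for peritubular and smooth muscle cells (mean 0.05, adjusted p = 0.524) and blood (0.19, adjusted p = 0.32) were not called. The peritubular mean joins opposite shifts, -0.30 within replicates 1 and 2 and 0.40 within replicates 3 and 4, where the list was called higher (adjusted p = 7.79e-06). It was also called higher with the replicate block and number 1 left out (0.25, adjusted p = 3.32e-05), with array weights (0.59, adjusted p = 0.000453) and without mutant replicate 2 (0.30, adjusted p = 0.0489). With array weights the spermatogonial, Sertoli and macrophage lists lost their calls (camera, adjusted p = 0.113, 0.99 and 0.169), the Sertoli mean being 0.01. The epididymis list had a mean of 0.16 while camera gave it a downward direction (adjusted p = 0.952) and an upward one with either block. The epididymis mean ran from -0.63 to 1.04 as each mouse was left out in turn without a block. This leaves the batches, which differed by 4.54 on this list, uneven between genotypes. Within replicates 1 and 2 the mean was 0.06. Within replicates 3 and 4 it was 0.26, and the list was called higher there (camera, adjusted p = 0.000239). Unequal tissue from outside the testis may thus add to somatic shifts within replicates 3 and 4, which was not tested. The endothelial shift was 0.245 within replicates 1 and 2 and 0.174 within replicates 3 and 4. For macrophages these shifts were 0.14 and 0.157.

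Among the 45 genes that rose with the replicate block, the largest changes were in genes of low intensity. Sox10, a transcription factor of the neural crest, rose 3.10-fold from 48.6 ± 25.7, and the receptor kinase gene Ltk 2.85-fold from 120 ± 37.4. Tex101, which encodes a germ cell surface protein, was abundant and rose 2.00-fold, from 9758 ± 1962 to 19694 ± 4916 (adjusted p = 0.00766 with the replicate block and 0.0864 without). Cplx1, Fcmr and Lpo rose between 1.99-fold and 2.03-fold (2 other kept probe sets of Cplx1 were not called), and the clone-named genes 4932441J04Rik and 6720468P15Rik 2.88-fold and 2.26-fold. These rises all missed the threshold without a block. Among the largest falls called with both blocks but not without one were Tex37 (11.1-fold) and Oxct2a (9.70-fold), the latter a ketone body enzyme gene of spermatids, and Fam71b, with a log2 difference of -3.33. Without mutant replicate 1 the log2 difference was -2.61 for Fam71b and -2.83 instead of -3.48 for Tex37.

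The remaining lists were not called without a block. Their means stand beside a median log2 difference of 0.065 over all genes tested. Camera's adjusted p was 0.792 for the BRWD family and other bromodomain genes (mean log2 difference 0.07), 0.792 for genes near Brwd1 on chromosome 16 (0.01, with -0.11 within replicates 1 and 2 and 0.14 within replicates 3 and 4), 0.808 for sex-linked genes silenced in meiosis (0.00), 0.348 for the p53 response (0.08) and 0.952 for the DNA damage response (0.01). It was 0.348 for cholesterol synthesis (0.09, but 0.15 and called higher with the mean of probe sets, adjusted p = 0.0342), 0.952 for chromatin modifiers of spermiogenesis (-0.01, with camera's direction upward) and 0.114 for the apoptosis machinery (0.09). The sex-linked list had a mean just above 0 with a downward direction in the test. Cytosolic ribosomal protein genes had a mean of 0.09 (adjusted p = 0.0972) and were called higher with the replicate block (0.0156), the batch block (0.0223) and without wild-type replicate 1 or mutant replicate 3 (0.0216 and 0.022), though not with an estimated correlation (adjusted p = 0.64 with the replicate block). In the heat shock and unfolded protein list (mean -0.29, adjusted p = 0.156) 3 genes fell with both blocks: Hspa1l and Calr3, chaperones of male germ cells, and Asns, which makes asparagine. No chromosome's genes shifted as a set (camera, smallest adjusted p = 0.989).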

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

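A mouse was set aside for a closer look where its gap to the nearest of the other 3 in its group, divided by the group's range, exceeded Dixon's critical value. Of 304 groups of named genes and list means, 14 met this. Chance gives about 1 in 20 for 4 draws from 1 normal distribution. Each group here joined 2 mice of each batch, so that rate need not hold. A gap between batches can also hide a mouse that stands apart. Mutant replicate 1 stood apart for Sox9 (497, others 373 to 391), Sox17 (1120, others about 1330), Rad54l (483, others 355 to 373), Calr3 (90.3, others 271 to 305) and Casp6 (881, others 666 to 671). Mutant replicate 2 stood apart for Fcmr (1330, others 828 to 888) and Kat8 (3850, others 2800 to 2870), and mutant replicate 3 for 4932441J04Rik (179, others 104 to 114). Wild-type replicate 4 stood apart for Sox8 (94.3, others 270 to 294), Tie1 (98.7, others 44.3 to 51.2) and Bcl2l2 (1110, others 791 to 842). Wild-type replicate 2 stood apart for Fam71a (512, others 351 to 373) and Cycs (3730, others 4500 to 4590), and wild-type replicate 1 for Des (524, others 180 to 198). No list mean met the criterion. None of the 64 AFFX control probe sets passed limma's test between genotypes, with or without the replicate block.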

How the results depend on the processing

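The batch block, the fits within a batch and the fits that pair a block with a left-out mouse were chosen after seeing the data. The count of 39 genes became 23 with a pseudocount of 1, 92 with 64, 22 with a filter at the 60th percentile, 697 with array weights, 475 with the replicate block, 363 with the batch block, 0 within replicates 1 and 2, 630 with the batch block and mutant replicate 1 left out, and 527 with the replicate block and number 1 left out. For the 39 genes with at least a 2-fold change these values were 23, 85, 22, 413, 334, 224, 0, 348 and 375. The 30 probe sets became 54 with a pseudocount of 64, 659 with array weights, 630 with the replicate block, 477 with the batch block, 0 within replicates 1 and 2, 689 with the batch block without mutant replicate 1 and 538 with the replicate block without number 1. At an adjusted p of 0.01 limma called 0 genes and 0 probe sets, against 1318 and 2001 at an unadjusted p under 0.05. The filter tests fewer genes and the fits within a batch use fewer mice; otherwise the cause was not tested. Leaving out each mouse gave 0 to 185 genes, 0 to 181 with at least a 2-fold change and 0 to 118 probe sets. For probe sets it gave 0 without wild-type replicate 1, 2 or 3 or mutant replicate 3 or 4, 12 without mutant replicate 2, 53 without wild-type replicate 4 and 118 without mutant replicate 1. The 11 gene lists (6 lower, 5 higher) became 7 after quantile normalization (6 lower, 1 higher), 7 within replicates 1 and 2, and 0 with an estimated correlation or with fry's directional test (its mixed test passed 2 lists, the multicopy and heat shock ones, at 0.0333 and 0.0228); the cause was not tested. The epididymis list changed its direction in camera within replicates 3 and 4 and was called higher there (mean 0.26, adjusted p = 0.000239). The cause was not tested. Brwd1 stayed uncalled in all 24 alternatives, with log2 differences from -0.05 to 0.68. Over the named genes, 2642 values under alternatives stayed called or stayed uncalled, 236 gained a call, 95 lost it and 0 were called in the opposite direction. For single lists the numbers were 597, 10, 67 and 1. Uncalled genes and lists, Brwd1 among them, changed sign in some alternatives. The paired fit changed no call other than those printed beside their results or counted here. Without detection calls, the limit set by signal over background is unknown.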

Other observations

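Epididymal transcripts made up some of the brightest signals of replicates 3 and 4 in both genotypes. Gpx5, a glutathione peroxidase of the epididymis, averaged 145.8 ± 162.8 in replicates 1 and 2 and 16380 ± 1436 in replicates 3 and 4 (SD, n = 4 each), and Lcn8 41.8 ± 27.6 and 12190 ± 525. Adam7 went from 62.5 to 6510 and Rnase10 from 40.4 to 8786. Svs5 was lower in replicates 3 and 4, with a log2 difference of -0.63. Peritubular and smooth muscle genes were higher there by 0.91 on average, and sex-linked genes silenced in meiosis by 0.84, with 19 of 27 passing the test, while the spermatid nuclear list differed by 0.19 with 0 members passing.

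Of the tests that follow, only the counts over other splits were planned before their results were seen; the tests on batches, on the spermatid list, on clone names and on lists in blocked splits were chosen after. Replicates 1 and 2 stood apart from replicates 3 and 4 on 10908 probe sets. The shape of the intensity distribution is argued against, since 11222 probe sets differed after quantile normalization. A different labelling run is consistent with the poly-A controls, added before labelling, whose median log2 difference was -3.41. The hybridization controls, added after labelling, were lower by 0.31 to 0.90, which a labelling run alone need not give. Epididymal tissue in replicates 3 and 4 may account for part of the split, the epididymis list being higher by 4.54 ± 0.17 (SE). A scaling to a common target acts alike on all probe sets of an array. The poly-A controls differed by -6.855 to -2.058 log2 units, further than any hybridization control. These values argue against extra tissue, acting through that scaling, as the whole source of the poly-A difference. Whether such tissue lowered the hybridization controls was not tested. Nor was any other biological explanation.

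The lower level of the spermatid nuclear protein genes in mutants did not come from mutant replicate 1 alone, since without it the batch-blocked shift was -1.89 ± 0.29 (SE). Each batch held 2 mice of each genotype, so a level that differs only between batches does not part the genotypes. The shift was -3.28 ± 1.45 (SE) within replicates 1 and 2 and -1.92 ± 0.49 within replicates 3 and 4. Both lie more than 2 SE below 0, the rule set for this test. With 2 mice against 2 that rule is a weak one, above all within replicates 1 and 2. A smaller share of late spermatid RNA should raise all other cell types alike, and this was tested in 2 forms. Over 7 lists, meiotic prophase and Leydig cells differed by 0.30 ± 0.06, which is 4.69 standard errors and under the bound of 5.67 for 21 pairs. The pattern set for a smaller share, all 7 lists higher and no pair over 2 SE apart, was not met either. Meiotic prophase shifted by -0.05 ± 0.06 (SE), and 3 pairs were over 2 SE apart. The test with 7 lists therefore does not decide. The form with 5 lists (largest difference 0.10 ± 0.14) decides nothing, since it held only the lists already called higher and left out those of meiotic prophase and peritubular cells. A change of share and a change of transcription in spermatids of Brwd1 mutants both stay open.

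Clone-named or predicted genes were frequent among the genes that fell. They made up 86 of 430 lower genes with the replicate block (20%) against 6.14% of all genes tested, an odds ratio of 4.14 (Fisher's exact test, two-sided, p = 3.78e-23), and 57 of 298 with the batch block, an odds ratio of 3.80. They were also 9 of the 45 genes that rose (odds ratio 3.85, exact p = 0.00143) and 9 of the 65 that rose with the batch block (odds ratio 2.47, exact p = 0.0173), so the excess was not limited to falls. Genes are not independent replicates, and no explanation of the excess was tested.

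Splits of the 8 mice into other groups of 4 give a measure of chance. Without a block, 2 of 35 splits, the real one included, gave as many genes as the real 39, so chance is not excluded by this count. The other split was that of replicates 1 and 2 against 3 and 4, with 5314 genes, which points to a structure of the samples. The same 2 splits were as large for the 30 probe sets (highest other 9964) and for genes with at least a 2-fold change (highest other 1016), and the blocked counts are 475 and 363. For the 11 gene lists 1 of 35 splits was as large, the real one, and the highest other gave 10, so the share is under 0.05 by a margin of 1 list. The lists were called at a preset correlation, and 7 passed after quantile normalization and 0 with an estimated correlation, so this does not settle whether chance gave them. With the replicate block 8 splits part all 4 pairs, and with the batch block 18 splits divide both batches evenly. Each real count was the largest, 1 split of 8 and 1 of 18, with 0 genes in the highest other, but so few splits cannot give a share under 0.05. For lists the real counts were 12 and 11 and the highest others 7 and 10, again 1 split of 8 and 1 of 18.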
